A study of Mus musculus with 2 samples.

How the data were processed

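Binding of the transcriptional repressor Gfi1 was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in group 2 innate lymphoid cells (ILC2s), sorted from the mesenteric lymph node of C57BL/6 mice given IL-25. Per the labels' protocols, about 30000000 cells were crosslinked with formaldehyde and sonicated, and fragments of 300 to 500 bp were recovered. The series has 1 ChIP sample, made with a custom rabbit polyclonal antibody against Gfi1 peptides, and 1 sample of input DNA. There are no replicates, so no value below has a replicate error.

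The data used were 1 list of 8707 peaks, each with a chromosome, a start, an end and a score, per the file headers. The score is the authors' own value for each deposited peak, and what it measures is not given in the sources used here. Reads were aligned with Bowtie 0.12.8 to mm10, per the submitters' processing notes. The peak caller, its threshold, how the input sample was used and the read depth of either library are not given in the sources used here, so the depth is unknown and no counting interval was put on any score. The lowest listed score was 10.0, and 100% of the scores were whole multiples of a step of 0.0597 (within 0.1 steps). The score was used only to rank, filter and describe peaks within this list. Coordinates are printed as deposited, on mm10, and whether they count from 0 or 1 is not stated. The list gives no summit, so a peak's position was the midpoint of its start and end.

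Genes came from a RefSeq table of GRCm38.p6, which is the same assembly as mm10. Of its 49997 rows, 49603 were used, after leaving out 340 with a start in the first 3 Mb of a chromosome and 54 on sequences with another name. As a check of the build, the share of peaks within 1 kb of an end of a protein-coding gene was 25.7% in place and between 5.60% and 6.81% after shifts of 5, 20 or 100 kb in either direction. The table holds no strand and no exons. Distances to a transcription start site, as designed, were therefore replaced by distances to the nearer end of a gene, which can be its start or its last base, and peaks were not split into exons, introns and untranslated regions. No genome sequence was used here, so a planned search of the peaks for 22 sequence motifs was not run, nor was the comparison of scores between peaks with and without the Gfi1 motif.

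Every choice of test, gene list and alternative below was fixed before the data were examined, unless it is said to have been chosen afterwards. The share of peaks within 1 kb of an end of any gene was compared with 1000 random placements of the peaks on their own chromosomes, outside the unsequenced first 3 Mb (on chromosome Y the whole span was used), with a one-sided permutation p. Other assembly gaps were not left out. Scores of peaks near and away from gene ends were compared by the difference of medians with 100000 permutations. A gene was called bound when the midpoint of at least 1 peak lay in its body or within 20 kb of it. A peak said to be at a list member, or a score given for one, belongs to this locus and can lie outside the gene. For 22 gene lists the number of bound members was compared with 10000 random lists of the same size, drawn from 21779 protein-coding genes matched on locus length in 20 bins. The p is two-sided, adjusted by the Benjamini-Hochberg method over the 22 lists, and called below 0.05. The lists hold 599 entries, of which 595 matched the gene table (Il26, Trac, Ighm and Tpsab1 did not). Differences in bound share between lists were tested with Fisher's exact test, two-sided, after removing shared members, with Benjamini-Hochberg adjustment over 8 pairs, and over 3 pairs where peaks near gene ends were left out. These differences are not matched on locus length and were added to the design after the peaks had been seen. Peaks and genes are not replicates: each p describes this 1 list of peaks, not the spread between mice or libraries.

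Genes were named by a fixed rule. It takes the 15 highest scoring peaks, named by the protein-coding gene that holds them or else the nearest one, and up to 10 members with the highest scoring peaks from each of the lists of ILC2, ILC3, ILC1 and known Gfi1 target genes. It also takes Gfi1 and Gfi1b, the 5 protein-coding genes with the most peaks, 1 or 2 members of every other list, and members of the 4 main lists without a peak. Some genes that the rule takes are not reported here. Genes named outside it are said to have been chosen after their values were seen.

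The test of random placements and the test of gene lists were tried on simulated data first. The comparison of scores and Fisher's exact test were not. In 20 simulated lists of 8707 peaks with 20% of peaks set at gene ends, 19.9% were recovered on average (18.8% to 21.1%). Over 21779 genes, all 20 simulated lists of 40 genes in which 40% of members were given a peak had p below 0.05, against 0 of 20 lists with none given. These peaks came on top of those the genes already had, and members were drawn singly. Smaller excesses and lists of neighbouring genes that share peaks were therefore not simulated. Alternatives were other distances and flanks, the nearest gene within 100 kb, protein-coding genes only, autosomes only, peaks of at least the median score, merged peaks, random lists without matching on length, and lists without peaks near gene ends. Computations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.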

Results

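The binding sites of Gfi1, a zinc finger repressor that the study names as a determinant of innate type 2 lymphocytes, were read from 1 ChIP-seq peak list. ILC2s are innate lymphocytes that secrete IL-5 and IL-13 and respond to the epithelial cytokines IL-25 and IL-33. The list came from 1 Gfi1 ChIP sample with 1 input DNA sample, without replicates, and held 8707 peaks on 21 chromosomes. The peaks had a median width of 295 bp (quartiles 209 and 414.5 bp) and covered 2.95 Mb. The authors' score had a median of 12.3 (quartiles 10.9 and 15.9), and 84.2% of peaks scored under 20. A score of at least 50 was reached by 270 peaks and a score of at least 100 by 66.

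Gfi1 peaks gathered at the ends of genes. Of the 8707 peaks, 2710 (31.1%) lay within 1 kb of an end of a gene, 4.78 times the 6.51% of random placements (range 5.62% to 7.32% over 1000 placements, one-sided permutation p = 0.001, the smallest they can give). A further 3995 peaks (45.9%) lay inside gene bodies, where random placement put 45.7% (permutation p = 0.41). Intergenic positions held fewer peaks than random placements did. Those outside genes but within 20 kb made up 17.1% against 22.1%, and those farther than 20 kb from any gene 5.94% against 25.6%. Since gene ends without strand hold both starts and last bases, the share at transcription start sites alone was not measured.

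The strongest peaks lay less often at gene ends than the weak ones. The median score was 11.8 for the 2710 peaks near gene ends and 12.7 for the 5997 others, a difference of -0.81 (permutation test, p = 1e-05, the smallest it can give). Among the 871 highest scoring peaks, 14.1% were near a gene end and 56.6% inside a gene body. Among 870 peaks with scores from 10.7 to 11.1, 38.4% were near an end, the highest share of 10 equal parts of the list, and 43.3% inside a body. Among the 871 lowest scoring peaks these shares were 33.5% and 47.0%. Of the 270 peaks with a score of at least 50, 152 (56.3%) lay inside gene bodies and 44 (16.3%) near gene ends. By width the order turned round, with medians of 316 bp near gene ends and 286 bp elsewhere (difference 30 bp, permutation p = 1e-05).

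**Figure D1:**
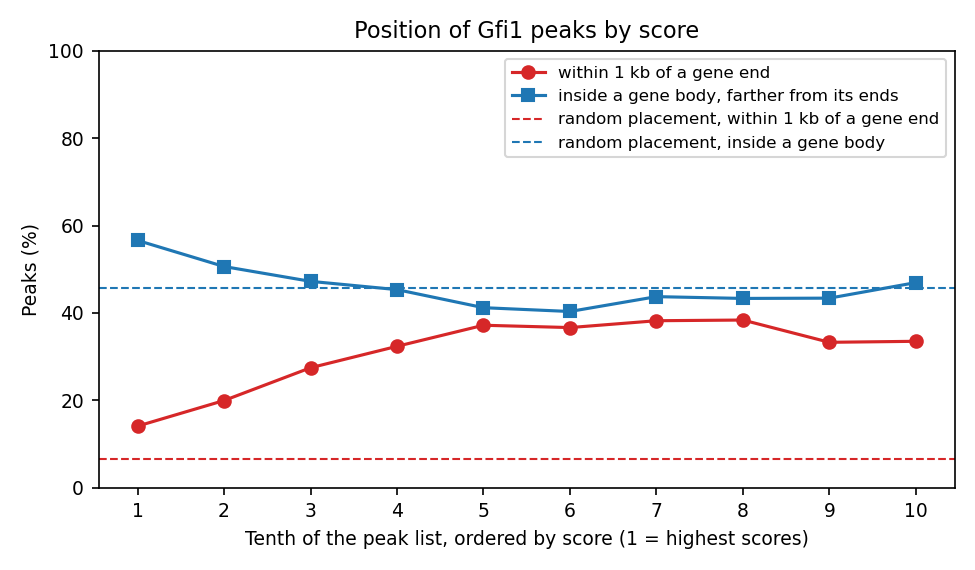
Share of Gfi1 peaks (%, vertical axis) within 1 kb of a gene end (red circles) and inside a gene body farther from its ends (blue squares) in each of 10 equal parts of the 8707 peaks, ordered from the highest scores (1) to the lowest (10), with the mean of 1000 random placements as dashed lines. The share near gene ends is 14.1% in part 1, 38.4% in part 8, its highest, and 33.5% in part 10, above the random 6.51% throughout.

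The strongest single peak, with a score of 644.5, lay on chromosome 13 from 17975828 to 17976548, 10.5 kb from Yae1d1. Cd200r3, a member of the CD200 receptor family, held a peak of 304 in its body (chromosome 16, 44965271 to 44965884). Cdc42bpb, a kinase that acts below Cdc42, held one of 272, and the mucin gene Muc3 one of 269. Inpp4b, a phosphoinositide phosphatase, held one of 235 (chromosome 8, 82025844 to 82026599). Itgae, the integrin alpha chain CD103 of intraepithelial lymphocytes, held one of 202 (chromosome 11, 73101354 to 73101700).

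Other strong peaks lay in the bodies of Alg14 (224), Myo16 (220), Chchd6 (214), Bcas3 (212) and Rnf144a (203). Among the 15 highest scoring peaks, the Alg14 peak was the only one within 1 kb of a gene end. Spty2d1 was the nearest gene to a peak of 338 (14.3 kb away) and Spef2 to one of 287 (22.2 kb away). The peak of 287, on chromosome 15 from 9555680 to 9556287, also lies beyond the 20 kb flank of Il7r, whose body ends at 9529941. It was not counted for Il7r. A pair of peaks with scores of 339 and 334 lay near the start of the sequenced part of chromosome 9, 299 and 320 kb from the nearest gene, Alkbh8. Their 100 kb window held 7 peaks, none of them inside a protein-coding gene, and without input coverage, which was not used here, binding there was not separated from a pile-up of repeated sequence.

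By number of peaks in the gene body and 20 kb flanks, Mroh2a led with 21 and Hjurp, a chaperone of centromeric histone, followed with 18. Sfi1, a centrosomal protein gene, had 17, Atxn1 had 12 and Arhgef3 had 11. Mroh2a and Hjurp overlap and share peaks in a crowded window on chromosome 1, and Sfi1 lies in another on chromosome 11. The Atxn1 peaks, with a top score of 171, lay outside both.

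Genes of ILC2s carried Gfi1 peaks far more often than other genes. Of 46 ILC2 genes, 40 (87.0%) had a peak in the gene body or 20 kb flanks, against a mean of 17.03 in random lists of matched length (central 95% of lists 11 to 23), a ratio of 2.35 (permutation p = 0.0002, the smallest it can give, adjusted p = 0.0011 over 22 lists). Among all 21779 protein-coding genes the share was 34.9%. The 40 bound ILC2 genes held 111 distinct peaks, and 22 of them had at least 3.

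Ptgdr2, the prostaglandin D2 receptor CRTH2, had the highest scoring peak of the list, with a score of 177 at 8.67 kb from its end (chromosome 19, 10915615 to 10916089). Nmur1, the receptor for neuromedin U, had 4 peaks with a top score of 122 (chromosome 1, 86394386 to 86394726). Il17rb, a subunit of the IL-25 receptor, had 3 peaks, the strongest in its body with a score of 55.1 (chromosome 14, 29997337 to 29997715). Tnfrsf9, the costimulatory receptor 4-1BB, had 5 peaks with a top score of 34.4, and Pcsk1, a prohormone convertase, had a peak of 41.7 at a gene end. Rora, a nuclear receptor required for ILC2 development, had 8 peaks with a top score of 27.0. Gata3, the leading transcription factor of ILC2s, had 1 peak in its body, with a score of 10.9, and was chosen after its value was seen. No peak was listed at Areg, Ets1, Ly6a, Rxrg, Tnfrsf18 or Dgat2.

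The genes of IL-4, IL-13 and IL-5, which lie together on chromosome 11, formed one of the densest groups of Gfi1 peaks. The 160 kb from 53590000 to 53750000 held 15 peaks with scores from 10.4 to 24.5. The loci of Il13 and Il4 held the same 9 peaks, each of them inside Il13 or nearer to it than to Il4. The strongest, at 53629188 to 53629692, lies 1.88 kb from Il13 and 10.8 kb from Il4. Il5 had 3 peaks, the strongest at 53719316 to 53719988 with a score of 18.7, 1.14 kb from the gene. Within Rad50, whose body holds the locus control region of these cytokine genes, 2 peaks had scores of 10.4 and 16.0. Il5 and Rad50 were chosen after their values were seen.

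**Figure D2:**
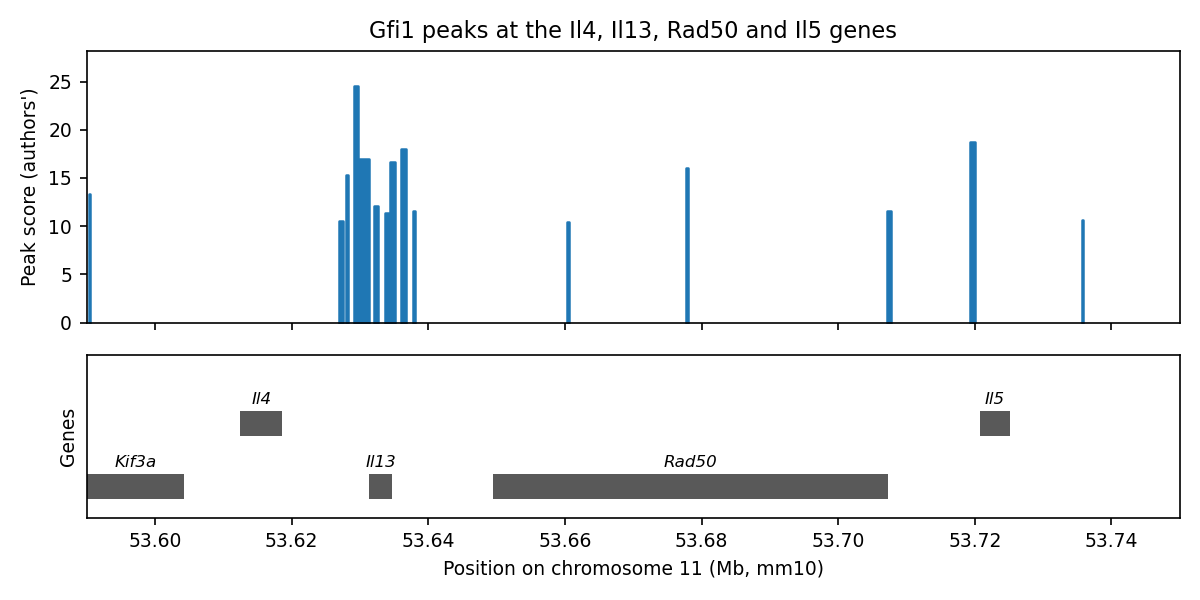
Gfi1 peaks on chromosome 11 from 53590000 to 53750000 (horizontal axis, Mb, mm10), each drawn at its width with the authors' score as its height, above the gene bodies of Kif3a, Il4, Il13, Rad50 and Il5. The 15 peaks crowd around Il13, where the highest score is 24.5.

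A second group of peaks covered the receptors of the IL-1 family on chromosome 1, where 10 peaks with scores of 10.0 to 45.1 lay from 40220000 to 40560000. Il1rl1, the IL-33 receptor ST2, had 6 peaks in its locus, and Il18r1, the IL-18 receptor, had 4. Their strongest peak was shared, with a score of 25.7 at 40474424 to 40474844, inside Il18r1 and 9.22 kb outside Il1rl1. Il1r1, the IL-1 receptor, held the highest peak of the region, with a score of 45.1 at 40284052 to 40284379. Il1rl2, also chosen after its values were seen, had no peak in its body.

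**Figure D3:**
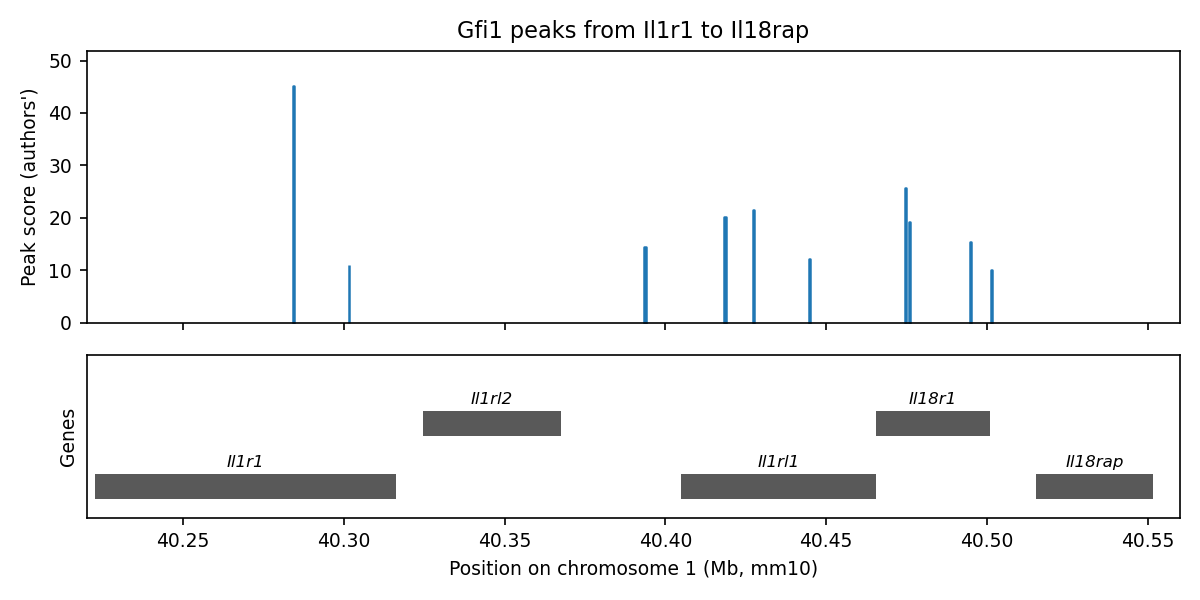
Gfi1 peaks on chromosome 1 from 40220000 to 40560000 (horizontal axis, Mb, mm10), each drawn at its width with the authors' score as its height, above the gene bodies of Il1r1, Il1rl2, Il1rl1, Il18r1 and Il18rap. The highest of the 10 peaks (45.1) lies in Il1r1, and 3 lie in the body of Il1rl1.

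Of 33 genes of ILC3s and Th17 cells, which make IL-17 and IL-22, 21 had a peak, against 12.2 in random lists (ratio 1.72, adjusted permutation p = 0.015). The list's call did not hold with flanks of 5 kb (15 bound against 8.53, adjusted permutation p = 0.051). Of 30 genes of ILC1s, natural killer cells and Th1 cells, 16 had a peak, against 10.99 (ratio 1.46, adjusted permutation p = 0.16). That list was called when peaks within 1 kb of gene ends were left out (14 bound against 6.33, adjusted permutation p = 0.0088) and when peaks were given to their nearest gene (14 against 7.39, adjusted permutation p = 0.025). Without shared members, the share of bound genes was 39 of 45 for ILC2s against 20 of 32 for ILC3s (Fisher's exact test, adjusted p = 0.036), and 40 of 46 against 16 of 30 for ILC1s (adjusted p = 0.0054). Without peaks near gene ends the difference from the ILC3 list no longer passed (36 of 45 against 19 of 32, Fisher p = 0.073 adjusted over 3 pairs). The difference between the ILC3 and ILC1 lists did not pass this test (20 of 31 against 15 of 28, adjusted Fisher p = 0.44).

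Among ILC3 and Th17 genes, Tox, a nuclear factor needed for innate lymphoid cell development, had 8 peaks with a top score of 83.5. Hif1a, the hypoxia-inducible factor, had 3 peaks with a top score of 70.4 in its body (chromosome 12, 73903803 to 73904746). The lymphotoxin genes Lta and Ltb shared a peak of 31.6. Ahr, the aryl hydrocarbon receptor, had a top score of 26.0, Cd4 one of 23.2, Batf one of 22.9, Sox4 one of 18.6 and Il17f one of 18.5. Il17a itself, chosen after its values were seen, had a peak of 13.3 at its end, and a stronger one of 45.3 lay 20.2 kb away, on chromosome 1 from 20754450 to 20754886, between Il17a and Il17f. No peak was listed at Il23r, a subunit of the IL-23 receptor.

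Tbx21, which encodes T-bet, the leading factor of type 1 lymphocytes, was the most strongly bound gene of the ILC1 list. Its 2 peaks lay in the gene body on chromosome 11, at 97103087 to 97103472 with a score of 69.2 and at 97103731 to 97104061 with a score of 40.4. Itga2, the integrin CD49b, had a top score of 47.1, and Ifng, which encodes interferon gamma, had a peak of 36.5 at 3.09 kb from the gene. The signal transducer Stat4 had a top score of 21.8, Nfil3 one of 19.2, Il12rb1 one of 17.8 and Klrb1c one of 16.5. Itga1 (13.4) and Runx3 (12.5) had weaker ones. No peak was listed at Eomes, Prf1, Gzmb or Cxcr3, the last of them on chromosome X, which held few peaks for its number of genes.

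Genes named in earlier work as Gfi1 targets had a peak in 23 of 46 cases, against 16.3 in random lists (ratio 1.41, adjusted permutation p = 0.11). The strongest were Itgae (202) and Ccnd1, the gene of cyclin D1, with a peak of 136 at 3.70 kb from its end. Ahr, Il7r (19.04), Meis1 (17.9), the cell cycle inhibitor Cdkn1a (17.6), Id2 (15.3), the apoptosis activator Bcl2l11 (14.6) and a peak shared by Rag1 and Rag2 (14.3) followed. Some of these genes, such as Ahr, Il7r and Id2, are also on the ILC2 or ILC3 list. The list was called with flanks of 5 kb (20 bound against 10.9, adjusted permutation p = 0.0094) and with peaks given to their nearest gene (21 against 10.3, adjusted permutation p = 0.0022). It was also called with peaks of at least the median score (16 against 8.97, adjusted permutation p = 0.041) and without peaks near gene ends (17 against 9.08, adjusted permutation p = 0.019).

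Gfi1 itself, a gene known to repress its own transcription, had 1 peak in its body and 20 kb flanks, with a score of 11.5. It lay on chromosome 5 from 107726084 to 107726556, at 0.515 kb beyond one end of the gene. The 100 kb window from 107700000 to 107799999 that holds the gene had 8 peaks, the others beyond the gene's 20 kb flanks. Gfi1b, the paralog of Gfi1, had no peak. Of 23 genes of corepressors known to bind Gfi1, 10 had a peak against 9.06 in random lists (adjusted permutation p = 0.97). Kdm1a, the histone demethylase LSD1, had one of 42.1, and Hdac3, a histone deacetylase, one of 20.3.

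Transcription factors of innate lymphoid cell development were bound in 24 of 30 cases against 12.2 (ratio 1.96, adjusted permutation p = 0.0011). Ikzf3, which encodes Aiolos, had 10 peaks with a top score of 147 (chromosome 11, 98501874 to 98502641), and Tox was next. Interleukins and receptors of type 2 responses, several of them also on the ILC2 list, were bound in 22 of 28 cases against 10.3 (ratio 2.14, adjusted permutation p = 0.0015). The strongest were Il17rb and the IL-13 receptor chain gene Il13ra1 on chromosome X, with a peak of 41.6. Genes of NF-κB and MAPK signalling below the IL-25 and IL-33 receptors were bound in 26 of 37 cases against 13.7 (ratio 1.89, adjusted permutation p = 0.0011). Without peaks within 1 kb of gene ends, 14 were bound against 7.69, and the call narrowly held (adjusted permutation p = 0.049). Irak3, an inhibitor of signalling by Toll-like and IL-1 receptors, had 5 peaks with a top score of 45.0, and the transcription factor Fos had 4 with a top score of 37.2.

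Genes of the TGF-β, Notch and Wnt pathways were bound in 18 of 22 cases against 8.996 (ratio 2.001, adjusted permutation p = 0.0015). Tgfbr2, a TGF-β receptor, had a top score of 65.0, and Apc, a regulator of β-catenin, a peak of 49.9. Cell cycle regulators were bound in 18 of 28 cases against 10.4 (ratio 1.73, adjusted permutation p = 0.018), led by Ccnd1 and by Ccnd2, the gene of cyclin D2, with a top score of 118. With peaks of at least the median score the cell cycle call was lost (9 bound against 5.77, adjusted permutation p = 0.35). Apoptosis genes were bound in 12 of 22 cases against 8.19 (adjusted permutation p = 0.22). Bcl2, which protects cells from apoptosis, had 7 peaks with a top score of 40.04, and its relative Bcl2l1 had 3 with a top score of 25.6.

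Ribosomal protein genes, which every cell uses, were bound in 19 of 28 cases against 8.86 (ratio 2.14, adjusted permutation p = 0.0011). Their strongest peaks scored 30.7 at Rps9 and 23.1 at Rpl18. The ILC2 list's difference from this list did not pass for its share of bound genes (adjusted Fisher p = 0.083). It did when peaks within 1 kb of gene ends were left out of both (37 of 46 against 10 of 28, Fisher p = 0.00049 adjusted over 3 pairs). That difference is not matched on locus length. Against matched random lists without those peaks, the ratio was 2.43 for ribosomal protein genes (adjusted permutation p = 0.019) and 3.72 for ILC2 genes. The difference therefore does not place the ribosomal peaks at gene ends alone.

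**Figure D4:**
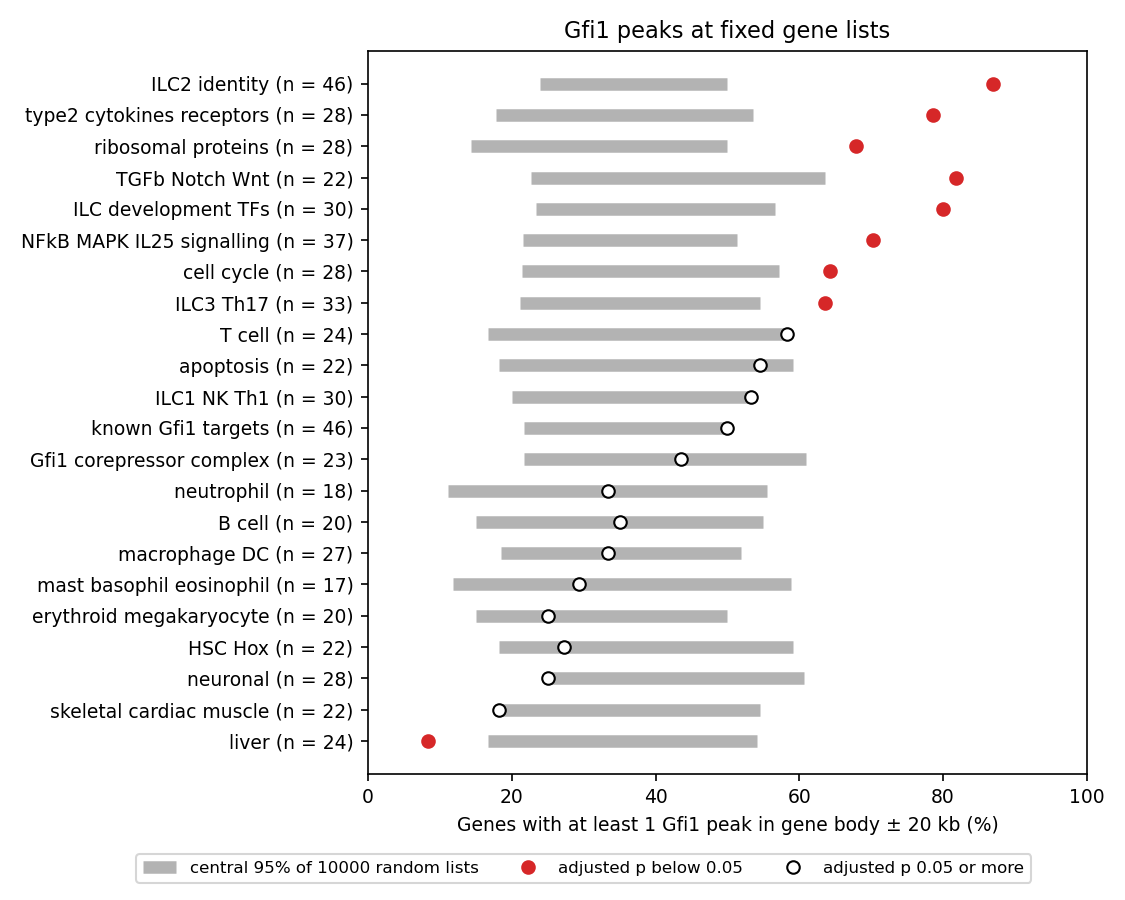
Percent of genes with at least 1 Gfi1 peak in the gene body or 20 kb on each side (horizontal axis) for the 22 gene lists, each with its number of genes, in order of the ratio to random lists. Grey bars span the central 95% of 10000 random lists of matched locus length, and filled red points mark the 8 lists above and the 1 list below them with an adjusted p below 0.05.

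The lists of T cells, B cells, macrophages and dendritic cells, neutrophils, mast cells with basophils and eosinophils, and erythroid cells with megakaryocytes were not called. Their differences from the ILC3 and Th17 list, which was called, were not tested. T cell genes were bound in 14 of 24 cases against 8.87 (adjusted permutation p = 0.11). Strong peaks lay 11.9 kb outside Cd6 (133) and in the body of Cd28 (51.1). The T cell list passed with peaks of at least the median score (12 bound against 4.93, adjusted permutation p = 0.0063). B cell genes were bound in 7 of 20 cases against 7.28 (adjusted permutation p = 1), led by Bach2 (29.8) and Pax5 (20.9), and macrophage and dendritic cell genes in 9 of 27 against 9.55 (adjusted permutation p = 1), led by Fcgr1 (26.0) and Ccr2 (20.6). Neutrophil genes were bound in 6 of 18 cases against 5.60 (adjusted permutation p = 1), with Ctsg (38.7) and Cebpe (14.2) first. Mast cell, basophil and eosinophil genes were bound in 5 of 17 cases against 6.03 (adjusted permutation p = 0.97). Their strongest peak, at Mcpt8, is the one at Ctsg, and Prss34 had one of 35.3.

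Erythroid and megakaryocyte genes were bound in 5 of 20 cases against 6.18 (adjusted permutation p = 0.97). Strong peaks lay in the body of Zfpm1 (63.9), which encodes the GATA cofactor FOG-1, and 10.9 kb outside Gata1 (60.9). Genes of haematopoietic stem cells and the Hox clusters were bound in 6 of 22 cases against 8.35 (adjusted permutation p = 0.58), led by Lyl1 (52.6) and Meis1. By Fisher's exact test the ILC2 list had a higher bound share than the T cell list (adjusted p = 0.023), the B cell list (adjusted p = 0.00012), the macrophage and dendritic cell list (adjusted p = 2.62e-05) and the mast cell, basophil and eosinophil list (adjusted p = 9.48e-05). The ILC2 list was not compared with called lists of similar share. These were TGF-β, Notch and Wnt genes (81.8%), factors of innate lymphoid cell development (80.0%) and type 2 interleukins and receptors (78.6%). A peak at a gene is no measure of its expression.

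Liver genes were bound less often than random lists, in 2 of 24 cases against 8.73 (ratio 0.229, adjusted permutation p = 0.011). The bound ones were Apoa2 and F2, the genes of an apolipoprotein and of prothrombin, each with a score of 11.5. The call was lost for gene bodies alone (1 bound against 3.69, adjusted permutation p = 0.31) and with flanks of 5 kb (1 against 5.82, adjusted permutation p = 0.051). Neuronal genes were bound in 7 of 28 cases against 11.5 (adjusted permutation p = 0.20), with Scn1a (40.5) and Stx1a (16.8) first, and passed as lower with flanks of 50 kb (8 against 14.7, adjusted permutation p = 0.041). Genes of skeletal and cardiac muscle were bound in 4 of 22 cases against 7.90 (adjusted permutation p = 0.20), with Ryr1 (58.8) and Tnnt3 (13.4) first.

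The autosomes held between 26.4 peaks per 100 protein-coding genes (chromosome 7) and 54.5 (chromosome 1). Chromosome X held 49 peaks, or 5.09 per 100 genes (exact Poisson 95% interval 3.76 to 6.73, for counting error only). The highest X score was 93.7, above those of the X peaks at Gata1 (60.9) and Il13ra1 (41.6). Chromosome Y held 13 peaks, of which 0% were near a gene end. Chromosome 11, which carries the type 2 cytokine genes, Itgae, Ikzf3 and Tbx21, had 768 peaks, or 47.9 per 100 genes, within that range. The planned rate was per Mb of sequence, and the rate per gene was chosen afterwards. Per Mb, chromosome 11 had the most peaks of all, 6.46, against 2.68 to 4.71 on the other autosomes and 0.292 on X.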

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

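The matching of random lists on gene ends nearby, the leaving out of peaks in the fullest windows of chromosomes 1 and 11 and in a window of 7 peaks at the start of chromosome 9, and the thinning of each list to 1 member per overlapping locus were chosen only after the results were seen. The gathering of peaks at gene ends kept its direction and call under all 6 alternatives run (ratios 2.99 to 7.96), and so did the ILC2 list under all 10 (ratios 1.77 to 3.72, adjusted p 0.00088 to 0.0044). Between 8 and 10 lists were bound more often than random lists throughout. Lists bound less often numbered 1, but 0 for gene bodies alone, 0 with 5 kb flanks and 2 with 50 kb flanks. Keeping peaks of at least the median score left 4406 of 8707 by construction, and merging neighbours left 8577. Peaks near gene ends had lower scores but were wider by 30 bp; the cause was not tested. Ratios of 7 lists not called in the report moved to the other side of 1 without passing the test, and the cause was not tested. For corepressors these were 0.799 (gene body), 0.592 (nearest gene), 0.760 (median score) and 0.961 (matched on gene ends nearby). For B cells they were 1.06 (gene body), 1.16 (5 kb), 1.002 (no matching), 1.19 (median score) and 1.36 (no gene-end peaks). For macrophages and dendritic cells they were 1.10 (50 kb), 1.31 (nearest gene), 1.14 (median score), 1.29 (no gene-end peaks) and 1.05 (overlapping loci thinned). For neutrophils they were 0.569 (gene body), 0.891 (5 kb), 0.995 (nearest gene) and 0.95 (no matching). For mast cells they were 1.51 (median score) and 1.22 (no gene-end peaks), for erythroid genes 1.12 (50 kb), 1.19 (median score) and 1.25 (no gene-end peaks), and for stem cell genes 1.06 (50 kb). Of the other alternatives for single lists, 174 kept direction and call, 8 gained a call and 4 lost one. The planned motif alternatives were not run because no genome sequence was used here, and the midpoint for a summit gives no second value since no summit is listed. No paired analysis was possible because each group has 1 sample. Read depth and the listing threshold are unknown, so a gene without a listed peak may only have one that scored under the lowest listed score of 10.0.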

Other observations

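The tests of gene families, of chromosome X peaks per gene, of list differences without gene-end peaks, of random lists matched on gene ends nearby and of the crowded regions were chosen only after the results were seen.

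Histone genes carried peaks in 40 of 57 cases (70.2%), against 6.45 in random lists matched on their short loci and 34.9% of all protein-coding genes. Neighbouring histone genes share peaks (H2ac7, H2ac8, H2bc7 and H2bc8 share one of 26.0 on chromosome 13), and counting 1 gene per overlapping locus gave 5 of 7 against 0.63 (adjusted permutation p = 0.0019 over 14 families), an excess that would be smaller against the share of all genes. Separate loci are counted by the 1 gene kept per overlapping locus, so a peak only at its neighbours does not count. Receptors of the TNF receptor superfamily were bound in 12 of 16 separate loci against 5.93 (adjusted permutation p = 0.020), led by Tnfrsf9 (34.4), Tnfrsf13b (18.0) and Tnfrsf1b (17.8). Sensory receptors were bound less often than random lists, with 10 of 215 separate loci of olfactory receptors against 26.8 and 3 of 187 of vomeronasal receptors against 47.1 (adjusted permutation p = 0.0019 for each). The other 10 families were not called by separate loci, and keratins only with all genes counted (8 of 49 against 17.1, adjusted permutation p = 0.030). Among them, 27 of 46 guanine nucleotide exchange factors had a peak against 18.9 (adjusted permutation p = 0.064), with Rapgef2 holding 10 peaks up to a score of 115, and 17 of 29 loci of interleukin receptors against 11.4 (adjusted permutation p = 0.11). Cish, a feedback inhibitor of cytokine signalling, had 8 peaks up to 24.8, and the chemokine receptor Ccr10 had 3 up to 49.5, both chosen after their values were seen.

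Chromosome X held 5.09 peaks per 100 protein-coding genes, below the lowest autosome (26.4), so a small number of genes on X does not account for its 49 peaks, where the autosomal rate gives 405. A single X copy, as in cells of male mice, may have lowered the X scores under the listing threshold. Autosomal peaks of at least 2 times the lowest score give an expected 63.6 X peaks when scaled by gene number, within the exact Poisson interval of 36.3 to 64.8, but 94.7 when scaled by length of sequence, outside it. Chromosome Y held 13 peaks with a median score of 18.0, 0% of them near a gene end. Without input coverage these were not separated from repeated sequence, so whether they show male cells was not tested. The sex of the mice is not given in the labels, and a score taken relative to input would not fall with copy number. The explanation by a single X copy therefore stays open. No biological explanation was tested.

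Peaks at ribosomal protein genes raise the question whether a general signal at the ends of active genes gives the peaks at gene lists. Without peaks within 1 kb of gene ends, bound ribosomal protein genes fell from 19 to 10, still above the central 95% of random lists (1 to 8). Bound ILC2 genes fell from 40 to 37 against 5 to 15. Bound genes of NF-κB and MAPK signalling fell from 26 to 14 against 3 to 13. Peaks within 1 kb of a gene end therefore do not make up the whole excess of any of these lists. Signal from the same ends that reaches farther would pass this filter. Gene-rich surroundings do not account for the ILC2 list either, since 40 bound genes stood against 9 to 22 in random lists matched also on gene ends nearby. Signal at active genes farther than 1 kb from their ends was not tested, as no expression or input values were used here. Binding of Gfi1 at ILC2 genes beyond their ends may contribute, as a hypothesis found and tested on the same peaks, beside that untested signal.

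Peaks crowded in 2 windows of 100 kb, with 27 on chromosome 1 between 88212420 and 88292545 (around Hjurp, Mroh2a and Ugt1a1) and 18 on chromosome 11 between 3105098 and 3200043 (around Sfi1), where no window of 1000 random placements held more than 8. Random spread does not account for that, and 4 more windows on chromosome 11 also passed 8, with 11 (Il4 and Il13), 10, 9 and 9 peaks. Reads from near-identical copies that the assembly lacks may pile up in the crowded windows. The median score of their peaks was 13.2 over both (12.5 on chromosome 1, with a median width of 401 bp, and 53.7 on chromosome 11, with 1339 bp), which decides nothing, and the explanation cannot be told apart from binding because no input coverage was used here. No biological explanation was tested.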
